A study of Mus musculus with 4 samples.

How the data were processed

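RNA from 4 bones of male C57BL/6 mice aged 35 days was measured on 4 Agilent whole mouse genome arrays, 1 array each for the ilium, the femur, the maxilla and the mandible. Total RNA was isolated with a column kit for lipid-rich tissue and labelled with cyanine 3 in 1 channel, per the labels' protocols. The labels do not say how many animals gave the RNA of a bone. With 1 array per bone there were no replicates of a bone, and the number of arrays limits the precision.

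The deposited array files hold spot intensity values on a linear scale, extracted with Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes and the file headers. The processed signal in them was background-subtracted and spatially detrended before deposit, per the file headers, with a surrogate value given to spots not above background. The same files give other fields per spot that the program set, among them whether a spot was well above background, saturated or an outlier. The deposited series table holds log2 values made with GeneSpring, per the series description. Set against the scanner values, each of its columns was the log2 ratio of an array to the ilium array minus a constant, within 0.001 for at least 99.6% of 41174 probes. The constants were 0.096 for the femur, -0.0955 for the maxilla and 0.1222 for the mandible, and the column medians were 0.0232, -0.217 and -0.133, with 0 for the ilium. How these constants were chosen was not given in the sources used here. Probe positions are those of the array design on the mouse genome build mm8, per the file headers.

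Of 43379 spots that were not controls, 72.8% were well above background for the ilium, 75.5% for the femur, 74.8% for the maxilla and 73.7% for the mandible, and 0 were saturated on any array. The 75th percentile of the processed signal was 1142 for the ilium, 1208 for the femur, 809 for the maxilla and 1142 for the mandible, and the median signal was 130, 140, 121 and 143 in the same order. Probes printed in several spots had a median SD between spots of 0.0568 to 0.073 on the log2 scale, which is technical error within an array only. All 4 arrays lay on 1 slide with 1 recorded scan time, so slide was no batch, while the position on the slide and the bone could not be told apart.

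Values were log2 of the processed signal minus the 75th percentile of the same array. Spots of 1 probe were averaged, and of several probes of a gene the one with the highest mean over the arrays was used. A probe with an outlier spot on any array was left out, by the rule set before the data were examined. Some probes were printed in several spots, and the rule then removed the whole probe for 1 outlying spot. It left 40 genes without a value, Wnt1 and Spp1 among them, and moved 29 genes to a dimmer probe, Ngfr among them. For these genes an alternative chosen after seeing the data averaged the remaining spots of the probe, and values from it are named as such. Of 41174 probes, 24375 were named by accession, 6301 by a current symbol and 2426 by an older symbol through a RefSeq gene table of assembly GRCm38.p6, used for names only, and 8072 kept the name in the file. This gave 27554 genes with a value. The 20583 genes well above background on at least 2 of the 4 arrays were tested.

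Jaw bones (maxilla and mandible) were set against trunk and limb bones (ilium and femur) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05). The bone was the unit, so the error was the spread between the 2 bones of a class, with 2 residual degrees of freedom, 1.758 prior degrees of freedom and a prior SD of 0.275 on the log2 scale. These p-values do not measure the spread between animals. A rule of size without a test counted genes whose lower value in 1 class exceeded the higher value in the other class by at least 1 on the log2 scale (2-fold). Maxilla against mandible and ilium against femur have 1 array each and no test, and genes there were counted at 4-fold or more by measured signal when well above background in the brighter bone. A second count, added after seeing the data, set a bone not well above background to the bound below. A gene not well above background on both arrays of a class has only a bound there. Its fold is given as at least the mean of the brighter class over the mean, per array, of the lowest signal well above background or the gene's own signal if that was higher, and the same was done between 2 bones.

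The 24 gene lists, with 393 entries, were fixed before the data were examined: neural markers of the study's qPCR, neural crest specifiers, jaw patterning genes, Hox genes, limb and girdle patterning genes, tooth matrix, osteoblast and osteocyte, osteoclast, cartilage, periodontal ligament and tendon, erythroid, neutrophil and myeloid precursor, B lymphocyte, megakaryocyte, skeletal muscle, stratified epithelium, nasal and salivary secretory, Schwann cell and peripheral nerve, adipocyte, cell cycle, Wnt, BMP and TGF-beta, immediate early and stress, and reference genes. For each list the median difference, its percentile among 10000 random lists of the same size matched on mean expression, and limma's camera with a preset correlation of 0.01 were computed. Random lists drew genes independently, so the percentiles take no account of correlation within a list or of the spread between samples. Camera was run again with an estimated correlation. The rule for named genes, also fixed before the data were examined, took the 12 largest gaps between the classes each way, the 6 genes of the study's qPCR, up to 4 members of each list with the largest class difference, and the 8 largest differences each way for maxilla against mandible and for ilium against femur. Names that are only clone or predicted-gene identifiers were passed over. Some genes that meet the rule are not reported here.

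The fit was tested on simulated data with 1 spread per gene, drawn from the prior fitted to the real arrays and shared by all 4 arrays. Genes were drawn independently. On the real arrays the SD of the difference was 1.33 for maxilla and mandible and 0.48 for ilium and femur. The rates below therefore hold only for the simulated setting. With 200 of 20583 genes changed, limma called 0 of the 66 changed 16-fold after adjustment, although all 66 had an unadjusted p under 0.05. A second simulation, with 3933 genes changed, as many as the size rule found, was added after that result; in it limma called 8.70% of genes changed 2-fold, 67.9% of those changed 4-fold, 89.6% of those changed 16-fold and 0.619% of 16650 unchanged genes. The size rule took 16.3%, 83.7%, 97.6% and 1.77% of the same genes.

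Alternatives planned before the data were examined were quantile normalization, median centring, normexp background correction of the mean and background signals with an offset of 50, the deposited series table, no filter on background, a filter on all 4 arrays, the mean of a gene's probes, outlier spots kept, an intensity trend or a robust prior in eBayes, camera with an estimated correlation, other fold thresholds, and leaving out each bone. Control spots were left out. The regenerated tissue, PCR, imaging and histology that the series description names were not analysed here.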

Results

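The series profiled gene expression in the maxilla, mandible, ilium and femur of 35-day-old male C57BL/6 mice, to ask how jaw bones, which were grafted beside the others in the same study, differ from bones of the trunk and limbs. Each bone had 1 array, and 20583 genes were well above background on at least 2 of the 4 arrays. Expression is given as log2 signal relative to the 75th percentile of the array. The ilium and femur were nearly alike, with a Pearson correlation of 0.989 across genes, whereas the maxilla and mandible had 0.907. Correlations between the classes ran from 0.828 for femur and maxilla to 0.919 for ilium and mandible. Genes are not independent replicates, so these correlations only describe the 4 arrays. The median absolute difference was 0.19 between ilium and femur, 0.45 between maxilla and mandible and 0.63 between the class means.

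The first comparison set the jaw bones against the trunk and limb bones. Tooth enamel and epithelial genes led the genes higher in the jaw, and Hox and slow or cardiac muscle genes led those lower. Ambn, which encodes the enamel protein ameloblastin (probe on chromosome 5, 89539748 to 89540277, mm8), was 2677-fold higher in the jaw bones, a log2 difference of 11.39 ± 0.97 (SE, 2 bones per class; adjusted p = 0.0327). Amelx, encoding amelogenin (chromosome X, 164524223 to 164525883), was 743-fold higher (9.54 ± 0.83, adjusted p = 0.0327; a second probe gave 7.5), and the basal keratin gene Krt5 was 689-fold higher (9.43 ± 0.46, adjusted p = 0.0327). Ckmt1 was 486-fold higher. Ctnna2 was called higher too, but its probe was not well above background in the ilium, and other Ctnna2 probes gave log2 differences down to 1.30. Enam, Mmp20, Serpinb5, Krt15 and Prom2 were not well above background in the ilium or the femur, and were at least 360-, 154-, 172-, 733- and 254-fold higher in the jaw. Fxyd4, also not well above background in either, had a fitted fold of 285. Its signals there (-6.28 and -6.32) exceeded the lowest signals well above background (-6.46 and -6.53), so that fold is no lower bound. A second Prom2 probe, well above background on 2 arrays, gave a smaller difference by measured signal. Dspp, which encodes the dentin matrix precursor, differed by 10.74 ± 1.93 but had an adjusted p of 0.0506. It was well above background in the ilium (-3.81) and not in the femur (-8.55), so its fitted difference is not exact.

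Among the 12 largest gaps in the other direction, 7 were Hox genes. Hoxc6 (chromosome 15, 102839635 to 102839696) and Hoxa10 (chromosome 6, 52161240 to 52161299) were not well above background in either jaw bone and were at least 24.7- and 25.7-fold higher in the trunk and limb bones (adjusted p = 0.0327 for both). Hoxc10, Hoxa9, Hoxb7 and Hoxa5 were at least 18.5-, 19.1-, 19.1- and 5.62-fold higher there, and Hoxc9 was lower in the jaw by limma (adjusted p = 0.0327), with a fitted difference of -7.15 that is not exact, since Hoxc9 was not well above background in the maxilla. The other 5 encode contractile proteins of slow or cardiac muscle. Myl2 differed by -6.58 ± 0.47, Myh7 by -6.09 ± 0.47, Tnni1 by -5.91 ± 0.38, Myh6 by -5.62 ± 0.28 and Tnnc1 by -4.64 ± 0.39, each past the limma threshold.

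Over all genes, limma called 923 higher and 1488 lower in the jaw bones, 2411 in total, so 38.3% of calls were higher. The size rule separated 1915 genes upwards and 2018 downwards, and 2399 genes met both criteria. The other 2 ways of splitting the 4 arrays into pairs gave 0 limma calls (42 and 123 genes at an unadjusted p under 0.05, against 7063) and 42 and 98 genes by the size rule. In those splits each pair joined a jaw bone with a trunk or limb bone. The class difference then fell within the pairs, which by itself lowers the limma and size rule counts. These counts therefore cannot show how many of the calls between the classes arise by error. With 3 splits, no share under 0.05 can be reached either. No adjusted p was below 0.0327, and leaving out the ilium or the femur left 0 limma calls (3539 and 2620 genes at an unadjusted p under 0.05), while leaving out the maxilla gave 6124 and the mandible 8169. Median centring or the deposited series table shifted the median of all genes from -0.03 to -0.28, and the share of calls higher in the jaw fell to 26.7% and 27.1%.

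**Figure D1:**
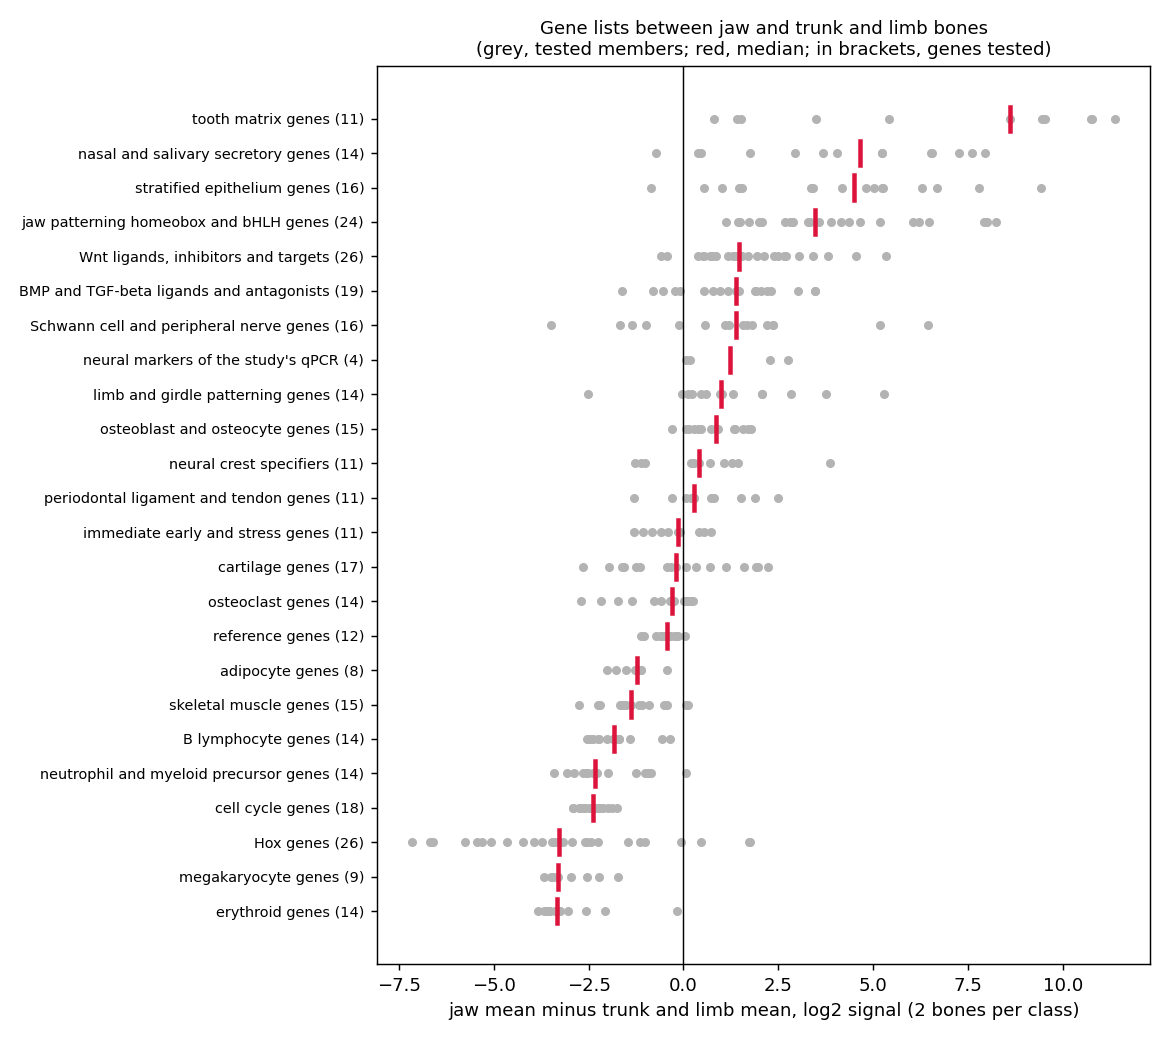
Difference between the mean of the 2 jaw bones and the mean of the ilium and femur, in log2 signal, for the tested members (grey) of 24 gene lists, with the list median in red. Medians run from -3.33 for erythroid genes to 8.61 for tooth matrix genes.

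Patterning genes separated the classes in opposite directions. Of 24 tested homeobox and bHLH genes of jaw patterning, 5 were higher in the jaw by limma and 0 lower, with 19 higher adjusted over the list alone and 19 by the size rule. Their median difference was 3.46, above all 10000 random lists. The jaw samples also held tooth matrix transcripts (median difference 8.61), and whether the patterning genes came from bone or from teeth was not tested. Lhx8, Msx2 and Dlx2 were not well above background in the ilium or femur and were at least 111-, 112- and 86.6-fold higher in the jaw, with adjusted p of 0.0327, 0.0444 and 0.0378. Alx1, not well above background in the femur, had a fitted difference of 6.46 ± 2.20 (adjusted p = 0.138), which is not exact. Of 26 tested Hox genes, 16 were lower in the jaw and 0 higher (21 lower adjusted over the list alone), with a median of -3.28, or -1.96 with the 15 genes not well above background in a whole class set to their bound. Camera with the preset correlation called both lists (adjusted p = 2.74e-09 each), and with an estimated correlation neither was called (adjusted p = 0.408 each). A filter on genes well above background on all 4 arrays removes by construction the Hox genes not seen in the jaw, and the list was then not called (median -0.53). With normexp the median of the Hox genes list was -0.64 and the list was called.

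Limb and girdle patterning genes were not lower in the jaw as a list. Their median difference was 0.99 over 14 genes, with 0 higher and 1 lower by limma and adjusted over the list alone, a preset camera adjusted p of 0.0475 and an adjusted p of 0.408 with an estimated correlation. The gene called lower, Tbx18, was not well above background in the jaw bones and at least 2.81-fold higher in the ilium and femur (adjusted p = 0.0327). Isl1 differed by 5.29 ± 1.13 (adjusted p = 0.0647), Pax1, not well above background in the femur, by 3.75 ± 1.09 (adjusted p = 0.107) and Tbx3 by 2.83 ± 0.62 (adjusted p = 0.0679). The Pax1 difference is thus not exact. The preset call of the list was lost without the maxilla and under quantile normalization.

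**Figure D2:**
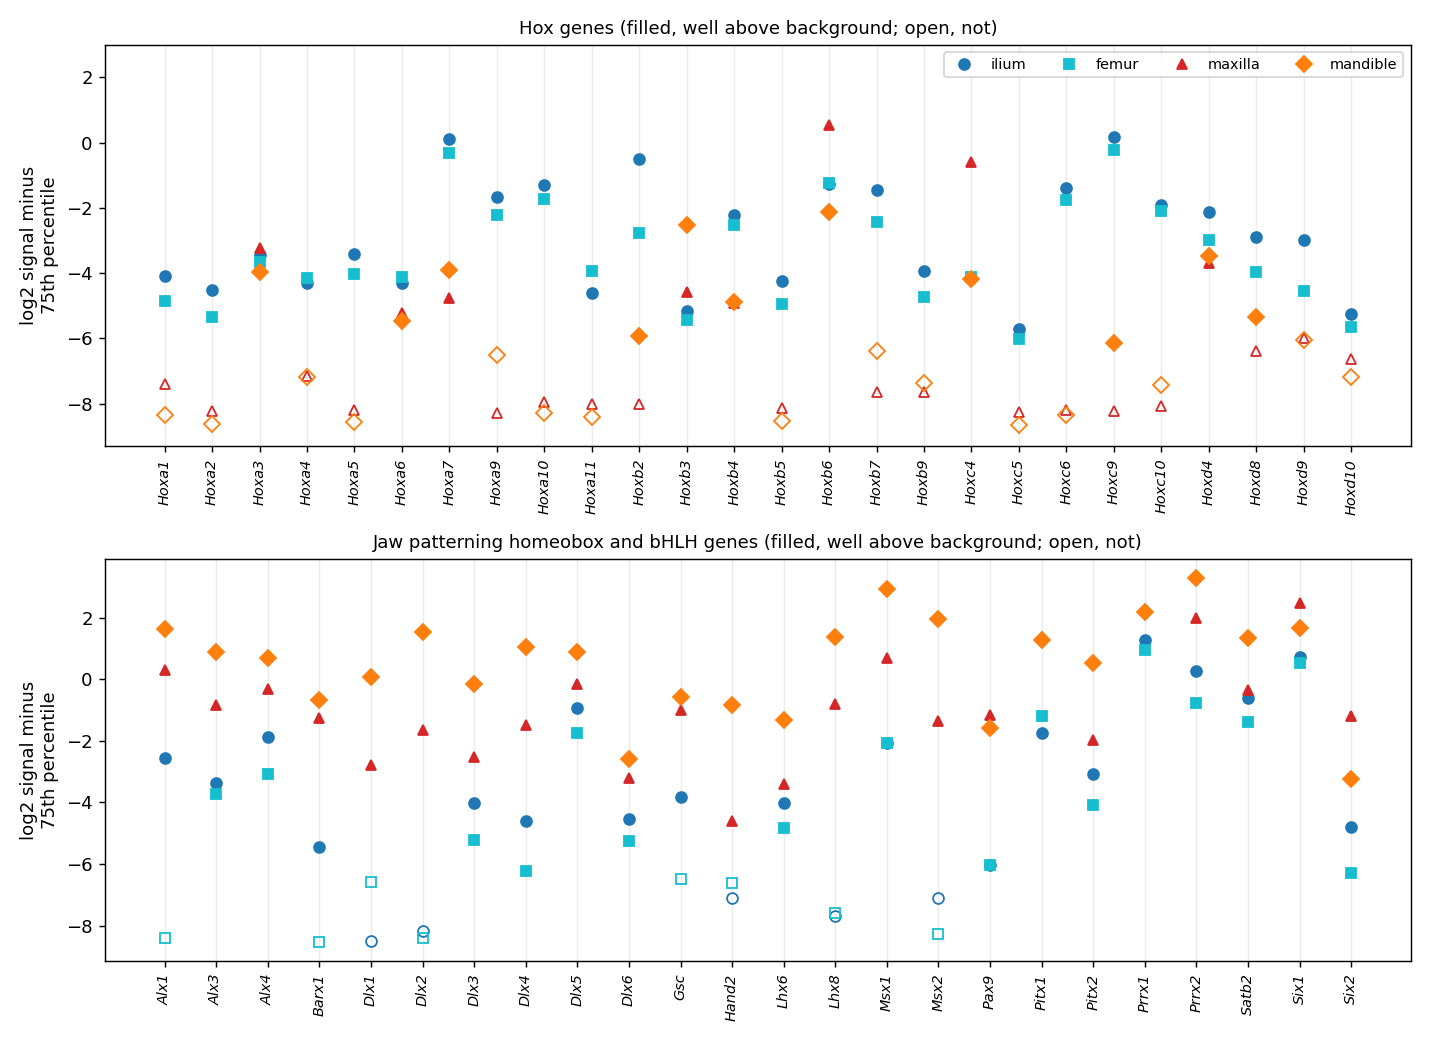
Log2 signal relative to the 75th percentile of the array for the 26 tested Hox genes and the 24 tested jaw patterning genes in each bone, 1 array per bone, with open symbols for values not well above background. Hoxc6 lies at -1.40 and -1.76 in the ilium and femur and at -8.19 and -8.35 in the maxilla and mandible, and Msx2 shows the opposite order with 1.96 in the mandible and -8.27 in the femur.

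Genes of teeth and of lining epithelium were higher in the jaw samples, and 12 of 14 nasal and salivary secretory genes were higher in the maxilla than in the mandible. Of 11 tooth matrix genes, 6 were called higher and 0 lower (9 higher adjusted over the list alone), with a median of 8.61, 7.27 with bounds in place of 4 genes, or 3.50 with the filter on all 4 arrays, which removes genes not seen in the ilium or femur. Of 16 stratified epithelium genes, 7 were called higher and 0 lower (9 adjusted over the list alone), with a median of 4.49, or 3.88 with a bound in place of 1 gene, and at least 2.85 over the alternatives. Krt14 differed by 7.78 ± 0.66, Krt17 by 6.69 ± 0.72 and Trp63, a regulator of basal epithelium, by 6.30 ± 0.48, each past the threshold, and other Trp63 probes, well above background on 2 arrays or fewer, gave smaller differences by measured signal. Preset camera called both lists (adjusted p = 8.91e-07 and 1.66e-06), and with an estimated correlation the adjusted p was 0.408 for both. Nasal and salivary secretory genes had a median of 4.65 with 1 of 14 called higher and 0 lower, by limma and adjusted over the list alone (preset camera adjusted p = 0.0197, and adjusted p = 0.519 with an estimated correlation). Their difference came from the maxilla: Dcpp1, Cyp2a5, Reg3g and Aqp5 had values of 4.16, 7.18, 7.23 and 5.25 there and of -5.33, -2.82, -2.68 and -4.48 in the mandible. Without the maxilla the median of this list was 0.83 and the list was not called, nor was it with the filter on all 4 arrays.

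Blood cell genes were lower in the jaw bones in each of 4 lineages. Erythroid genes had a median of -3.33 with 13 of 14 called lower, megakaryocyte genes -3.31 with 8 of 9, neutrophil and myeloid precursor genes -2.32 with 9 of 14 and B lymphocyte genes -1.84 (-1.81 with a bound for 1 gene) with 10 of 14, and 0 were called higher in any of them. Adjusted over the list alone the counts were 13, 9, 12 and 12. Rhag, a red cell membrane protein gene, was 14.3-fold lower (-3.84 ± 0.39), Klf1, an erythroid transcription factor gene, 12.3-fold lower (-3.62 ± 0.46) and Itga2b, a platelet integrin gene, 12.7-fold lower (-3.67 ± 0.31). Prtn3 differed by -3.41 ± 0.39, Mpo by -2.87 ± 0.43 and Pax5 by -2.25 ± 0.24, each past the threshold. All 18 cell cycle genes were lower by the size rule, 10 by limma and 18 adjusted over the list alone (median -2.38). Ccnb2 differed by -2.92 ± 0.44 and Mcm2 by -2.72 ± 0.39 (adjusted p = 0.0403 and 0.0383), while Plk1 differed by -2.91 ± 0.53 with an adjusted p of 0.0518. Preset camera called all 5 lists, with adjusted p from 2.44e-08 to 2.05e-06, but with an estimated correlation the adjusted p was 0.408 for the 4 blood lists and 0.491 for the cell cycle list.

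Osteoclast genes had a median of -0.30 with 4 of 14 called lower and 0 higher (4 adjusted over the list alone). The 4 were Car2 (-2.70 ± 0.30), Itgb3 (-2.16 ± 0.24), Mmp9 (-1.74 ± 0.30) and Tcirg1 (-1.35 ± 0.23); Car2 is also expressed in red cells and Itgb3 in platelets. The list's preset camera adjusted p was 0.0475, and its adjusted p was 0.53 with an estimated correlation. Without the ilium the median was 0.09, and the preset call was also lost without either jaw bone and under quantile normalization, median centring, the series table and the filter on all 4 arrays, with adjusted p from 1.34e-05 to 0.937 over all alternatives. Adipocyte genes had a median of -1.22, with 2 of 8 called lower (Adipoq, -2.02 ± 0.23, and Pparg, -1.77 ± 0.25), 0 higher and the same counts adjusted over the list alone, a preset camera adjusted p of 0.0208, and an adjusted p of 0.519 with an estimated correlation. Without the ilium or without the maxilla the adipocyte list was not called.

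For bone-forming cells, 0 of 15 osteoblast and osteocyte genes were called by limma, with 0 adjusted over the list alone and 5 at an unadjusted p under 0.05, although 14 had a positive difference. The median was 0.86, or 0.24 without the femur (preset camera adjusted p = 0.00911, not called without the mandible, and adjusted p = 0.519 with an estimated correlation). Omd differed by 1.77 ± 0.48, Phex, which regulates phosphate, by 1.71 ± 0.55 and Alpl, the tissue alkaline phosphatase gene, by 1.35 ± 0.28, with adjusted p of 0.0939, 0.125 and 0.0616. Periodontal ligament and tendon genes had a median of 0.28 with 1 of 11 called higher, the matrix gene Postn (1.88 ± 0.33, adjusted p = 0.0487), and 2 adjusted over the list alone (camera adjusted p = 0.0655 preset, and adjusted p = 0.53 with an estimated correlation). This list was called without the ilium, without the maxilla, and under quantile normalization, median centring and the series table, and its adjusted p ran from 0.00537 to 0.679 over the alternatives. Wnt pathway genes had a median of 1.47 (1.38 with bounds for 2 genes, 0.88 with normexp) with 2 of 26 called higher and 13 adjusted over the list alone, and BMP and TGF-beta genes 1.39 with 0 of 19 called by limma, 5 adjusted over the list alone and 8 at an unadjusted p under 0.05 (7 higher, 1 lower). Both lists were called with the preset correlation (adjusted p = 1.32e-06 and 0.0111), and the adjusted p was 0.408 and 0.517 with an estimated correlation. The BMP and TGF-beta list was not called without the mandible. Which tissue of the jaw samples the genes of these 2 lists came from was not tested. Sfrp2 differed by 4.54 ± 0.84, Wnt10a by 3.80 ± 1.17 and Bmp7 by 3.48 ± 0.66, with adjusted p of 0.0528, 0.116 and 0.0544.

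Cartilage genes had a median of -0.19 and a mean of -0.07, while camera pointed upwards without a call (adjusted p = 0.896). By limma 0 of 17 were called, with 0 adjusted over the list alone and 1 at an unadjusted p under 0.05. Without the ilium the median was 1.22 (preset adjusted p = 0.00327) and without the femur -2.03 (preset adjusted p = 0.000218), and the adjusted p reached 0.971 among the alternatives. Skeletal muscle genes had a median of -1.39 with 0 of 15 called by limma, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and a preset camera adjusted p of 0.0655. Camera called it without the mandible (median -2.71), without the femur, with normexp and with no filter on background, while without the maxilla the median was -0.05 (adjusted p = 0.986). Of this list, Actn3 stood at 5.58 and 5.60 in the ilium and femur, 1.25 in the maxilla and 4.43 in the mandible. Immediate early and stress genes had a median of -0.14 and 0 of 11 limma calls, with 0 adjusted over the list alone and 3 at an unadjusted p under 0.05 (preset camera adjusted p = 0.431). Reference genes had a median of -0.44 and 0 of 12 limma calls, with 0 adjusted over the list alone, 3 at an unadjusted p under 0.05, a preset camera adjusted p of 0.0412 and an adjusted p of 0.408 with an estimated correlation. That call was lost when any bone but the maxilla was left out and under quantile normalization. B2m differed by -1.12 ± 0.25 (adjusted p = 0.0679), and its other probes gave -0.52 and -1.74.

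The study also chose 5 neural crest and neural stem cell markers for PCR in these bones, with Gapdh as control. On the arrays, 0 of the 4 with a value were called by limma, with 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and a preset camera adjusted p of 0.221. Because the study picked these markers in the same work, they are not independent evidence. Sox10, a neural crest transcription factor gene (chromosome 15, 78982330 to 78982389), stood at 1.35 in the maxilla but at -2.45 in the mandible, -3.41 in the ilium and -3.18 in the femur, a class difference of 2.75 ± 1.40 (adjusted p = 0.257). Nes, encoding nestin (chromosome 3, 88066313 to 88066372), stood at 3.44 in the mandible, 1.24 in the maxilla, 0.22 in the ilium and -0.10 in the femur, a difference of 2.28 ± 0.83 (adjusted p = 0.154). For Ngfr, which encodes p75, the probe kept by the rule gave 0.06 ± 0.32 (adjusted p = 0.915), a sign that turned under quantile normalization, median centring and the series table, and without the ilium or the mandible. Its brighter probe had 1 or more outlying spots, and with only those spots left out it gave 2.70 ± 0.56 (adjusted p = 0.0621), with -2.84 and -2.38 in the ilium and femur and -0.59 and 0.77 in the maxilla and mandible. The brighter Msi1 probe gave 0.18 ± 0.22 (adjusted p = 0.583; negative under median centring and the series table), and a dimmer one gave 2.11. Wnt1, read in the same way as the brighter Ngfr probe, stood at -3.48 in the ilium, -3.29 in the femur, -3.92 in the maxilla and -4.74 in the mandible, a difference of -0.94 ± 0.36 (adjusted p = 0.167). Gapdh differed by -1.04 ± 0.41 (adjusted p = 0.171), a direction it kept under each scaling.

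Neural crest specifiers had a median of 0.42, with 1 of 11 called higher and 0 lower, and 1 higher and 1 lower adjusted over the list alone (preset camera adjusted p = 0.221). The gene called was Sox9, also a regulator of cartilage (3.88 ± 0.54, adjusted p = 0.0368), whose other probes gave 4.17 and 1.74. Snai2 differed by 1.45 ± 0.46 and Snai1 by 1.28 ± 0.63, with adjusted p of 0.124 and 0.247. Schwann cell and peripheral nerve genes had a median of 1.38, with 4 of 16 called higher and 2 lower (7 and 4 adjusted over the list alone), a preset camera adjusted p of 0.0475 and an adjusted p of 0.408 with an estimated correlation. The call was lost when any bone but the ilium was left out, with normexp and with the filter on all 4 arrays. Nefl and Gap43, genes of neurons and their processes, were not well above background in the ilium or femur and were at least 32.1- and 10.3-fold higher in the jaw (adjusted p = 0.0464 and 0.0337). Gfap was lower (adjusted p = 0.0327), with a fitted difference of -3.49 that is not exact, since it was not well above background in the maxilla, and a probe well above background on all 4 arrays gave -1.07.

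The maxilla and the mandible were then set against each other, with 1 array each and no replicate check. By measured signal 1885 genes were 4-fold higher in the maxilla and 521 in the mandible, and 1624 and 447 were at least 4-fold apart with a bone not well above background set to its bound, a count added after seeing the data. The 8 largest differences towards the maxilla were genes of secreted proteins of the nose and glands. The lipocalin genes Lcn3 (chromosome 2, 25588129 to 25588363) and Lcn4 had values of 6.41 and 6.93 in the maxilla and were not well above background in the mandible, which makes them at least 7187- and 10310-fold higher. Obp1a, an odorant binding protein gene, was at least 1385-fold higher, Scgb1b27 at least 3745-fold and Pnliprp1 at least 3007-fold. The major urinary protein genes Mup1, Mup5 and Mup6 were also among the 8, but the members of this family are near-identical in sequence, so single genes of it are uncertain. Mup1 stood at 7.10 in the maxilla and -5.35 in the mandible. The nasal and salivary secretory list had a median difference of 8.22, above all 10000 random lists, and 10 of its 14 genes were at least 4-fold higher in the maxilla.

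Towards the mandible, the leading genes were mixed. Shh and Vwa2 stood at 0.88 and 0.21 in the mandible and at -3.30 and -3.99 in the maxilla. Jsrp1, a gene of the muscle calcium-release machinery, stood at 1.96 and -2.61, and Dlk1 at 2.15 and -1.79. Grn stood at 7.08 and 3.17, although its class differences by probe were -1.78 and -0.66. Ucp1, the uncoupling protein gene of brown fat, stood at -0.45 and -4.96. Scube3 and Amy2 were not well above background in the maxilla and at least 4.89- and 6.73-fold higher in the mandible. Skeletal muscle genes had a median of -2.64 (maxilla minus mandible), with 12 of 15 at least 4-fold higher in the mandible. Jaw patterning genes had a median of -1.51, with 10 of 24 at least 4-fold higher in the mandible, and cell cycle genes -0.92, and these lists, like the BMP and TGF-beta list (-1.20) and the Wnt list (-0.75), lay at percentile 0 of the random lists. With normexp background correction the counts fell to 1043 and 261, and with genes well above background on all 4 arrays to 839 and 358.

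**Figure D3:**
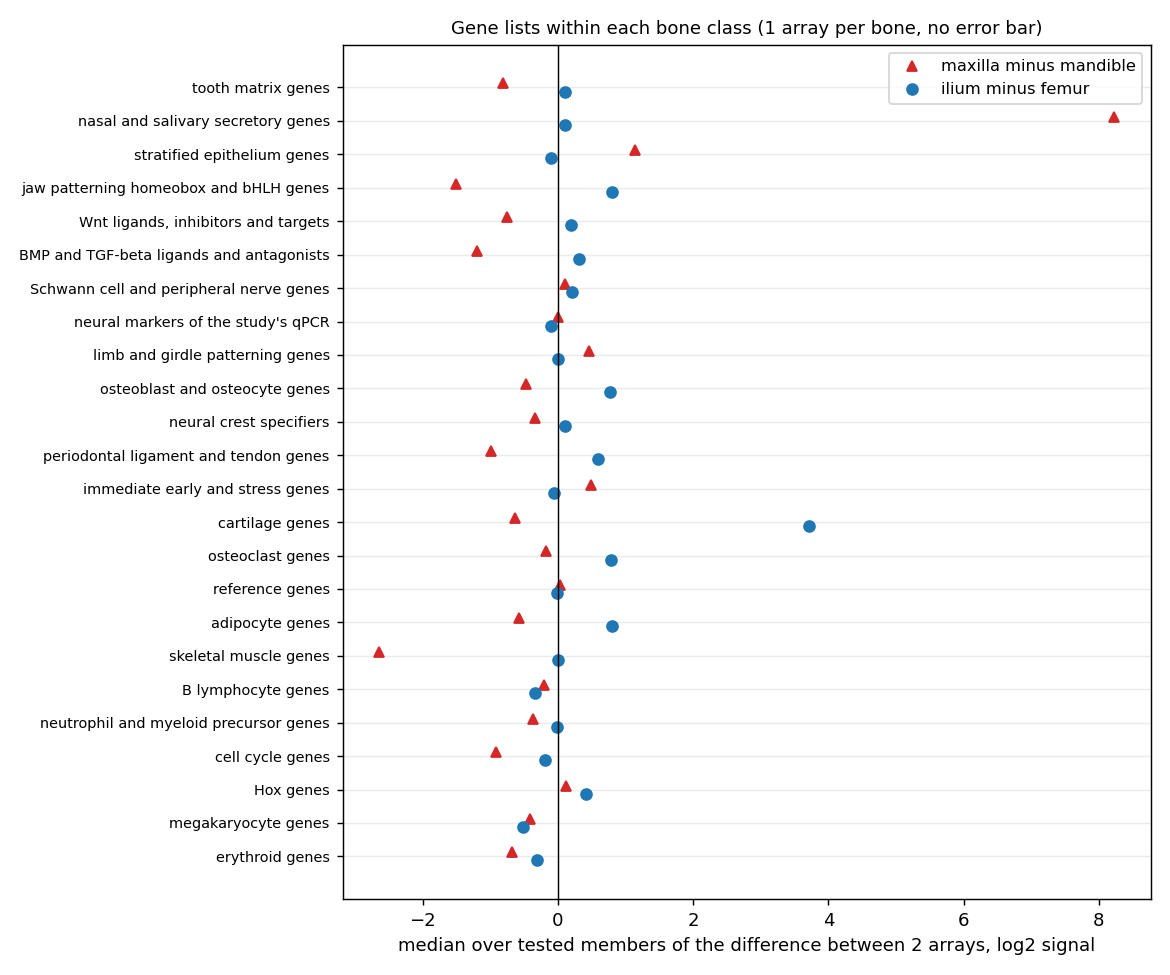
Median over tested members of the log2 difference between maxilla and mandible (triangles) and between ilium and femur (circles) for the 24 gene lists, 1 array per bone and hence no error bar. Nasal and salivary secretory genes stand at 8.22 for maxilla minus mandible, and cartilage genes at 3.71 for ilium minus femur.

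Of the 24 lists, cartilage genes differed most between the ilium and the femur. The cartilage list had a median difference of 3.71 (ilium minus femur), above all 10000 random lists, and 15 of 17 tested genes were at least 4-fold higher in the ilium and 0 in the femur. Smaller medians above all random lists were those of adipocyte (0.79), jaw patterning (0.79), osteoclast (0.79), osteoblast and osteocyte (0.76), periodontal ligament and tendon (0.60) and Hox genes (0.41). Megakaryocyte (-0.51), B lymphocyte (-0.33), erythroid (-0.31) and cell cycle genes (-0.20) lay at percentile 0. With correlated genes and 1 array per bone, a small shift shared by a list can reach such a percentile, so these percentiles are no test. Cnmd, which encodes chondromodulin (chromosome 14, 78379627 to 78384481), and Matn3, a cartilage matrix protein gene, were not well above background in the femur and were at least 48.2- and 12-fold higher in the ilium. Snorc, a cartilage proteoglycan gene, stood at 1.76 in the ilium and -4.97 in the femur, and Cytl1 at 2.22 and -3.27. Ucp1 was at least 213-fold, Bpifa1 at least 25.5-fold, Alx1 at least 15.6-fold and G6pc2 at least 12.1-fold higher in the ilium. Bpifa1 and Alx1 were higher still in the maxilla (7.33 and 0.31, against -1.86 and -2.56 in the ilium), while G6pc2 was not well above background in either jaw bone. Whether a trace of maxilla RNA in the ilium sample raised Bpifa1 or Alx1 was not tested. In all, 143 genes were 4-fold higher in the ilium and 63 in the femur by measured signal, but only 91 and 17 were at least 4-fold apart at the bound described above. Of the 8 largest differences towards the femur, Spata46, Clec2e, S100a7l2, Mab21l2 and Olfr835 were dim in the ilium and had bounds of 1.46- to 4.82-fold. Ghrl stood at -2.58 in the femur and -5.26 in the ilium, and Olfr282 at -1.98 and -4.75. With normexp background correction, which compresses dim signals, 33 and 2 genes were past 4-fold in each direction, and with genes well above background on all 4 arrays 50 and 8.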

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

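Leaving out only the outlying spots of a probe was chosen after seeing the data, and it moved 0 of the counts by over 1.5 times (2423 limma calls against 2411). The 2411 limma calls between the classes stayed within 1.5 times under quantile normalization (1897), median centring, normexp, the series table, the filter on all 4 arrays, the mean of probes, outlier spots kept and both eBayes options (2246 with a robust prior, 3100 with an intensity trend), and 1005 genes were called with no filter on background (361 higher, 644 lower), where more genes are tested. Calls higher in the jaw, 923, were 591 with quantile normalization, 599 with median centring and 569 with the series table. The last 2 differ from the main values by 1 constant per array, for nearly all probes in the series table. They moved the median of all genes from -0.027 to -0.279 and -0.281, which lowers the calls upwards. For quantile normalization the cause was not tested. Leaving out each bone gave from 0 to 8169 limma calls in all (0 to 4030 higher, 0 to 4139 lower), with 0 without the ilium or the femur, 6124 without the maxilla and 8169 without the mandible. A lone bone of a class is then assumed to vary like the other class, which differs more for the jaw pair. The size rule gave 4231 to 6824 genes under the same omissions (2098 to 3625 higher, 2133 to 3199 lower), since fewer arrays have to part. Normexp lowered its genes higher in the jaw from 1915 to 1200, and a 4-fold gap left 1194 genes (643 higher, 551 lower). The 2406 genes 4-fold apart by measured signal between maxilla and mandible were 2071 with bones not well above background at their bound, an alternative also chosen after seeing the data, 1304 with normexp (1043 and 261), 1197 with the filter on all 4 arrays (839 higher in the maxilla) and 5295 at 2-fold (3445 and 1850). The 206 genes between ilium and femur were 108 at the bound (91 and 17), 35 with normexp (33 and 2), 58 with the filter on all 4 arrays (50 and 8) and 1081 at 2-fold (514 and 567). The 2-fold and bound counts follow from their rules, and the cause of the others was not tested. Camera called 18 of 24 lists with the preset correlation and 0 with estimated ones (adjusted p of at least 0.408). The estimated runs rest on 2 residual degrees of freedom, so they could hardly call a list. Tooth matrix and stratified epithelium genes had estimated correlations of -0.0274 and 0.006, not above the preset 0.01. Their unadjusted camera p was still 0.0322 and 0.0361. For these 2 lists the loss of calls therefore does not show that correlation between genes removes the result. Limb and girdle patterning (-0.0309) and Schwann cell genes (-0.0044) also had low estimates. Those of cell cycle (0.979), megakaryocyte (0.894), erythroid (0.698), jaw patterning (0.327) and Hox genes (0.162) were above the preset 0.01. For such lists the preset camera p-values may be too small. Without the ilium the median of the osteoclast list turned from -0.30 to 0.091 (adjusted p = 0.937) and that of the cartilage list from -0.19 to 1.22 (adjusted p = 0.00327), and over the omitted bones they ran from -0.957 to 0.091 and from -2.03 to 1.22. Of 110 class differences of named genes, 104 kept direction and side of the threshold under quantile normalization, 105 under median centring, 96 under normexp and 94 with no filter; 59 calls were lost without the ilium and 59 without the femur. Some uncalled differences changed sign. Ngfr gave -0.290 with quantile normalization, -0.195 with median centring, -0.197 with the series table and -0.277 to 0.391 over the omitted bones, and Msi1 gave -0.0684 with median centring and -0.0699 with the series table. Cnmd ran from -1.44 without the femur to 5.40 without the ilium, Cilp from -2.94 without the mandible to 0.320 without the maxilla, and over the omitted bones the median of the immediate early and stress list from -0.717 to 0.352. Calls of Tcirg1, Msx2, Nefl, Mmp9 and Postn were lost under at least 3 settings that kept all bones. No paired analysis was possible because each bone has 1 array and the labels give no replicate numbers. Signal over background limits the dim genes: the lowest signal well above background lay between -6.53 and -6.02 on the scaled log2 axis, and differences below it are bounds.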

Other observations

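The tests of the Schwann cell, carried-over RNA, scaling and marrow explanations were chosen only after the results they bear on had been seen. The bounds for gland tissue and brown fat were set before the values of their lists were examined. The Sox10 and Ucp1 differences that they were to explain had already been seen in these arrays. The values of genes with outlying spots also come from an alternative chosen after seeing the data.

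Some list genes had no value, or a dimmer probe, because of an outlying spot. With only such spots left out, Nefm, a neurofilament gene, was well above background in the mandible alone, at -3.29. Read the same way, the brighter probe of Pax3, a neural crest specifier gene, stood at -1.18 in the maxilla and -4.02 in the mandible and was not well above background in the ilium or femur (limma adjusted p = 0.0614). Spp1, the osteopontin gene, stood at 7.37 in the ilium, 6.35 in the femur, 7.75 in the maxilla and 7.31 in the mandible (adjusted p = 0.357).

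Sox10 was 3.80 higher in the maxilla than in the mandible on the log2 scale. More Schwann cells in the maxilla sample would raise their other genes by about as much. The median of the Schwann cell and peripheral nerve list, maxilla minus mandible, was 0.103 (SD over 16 genes 1.35). Of the 16, 1 was 4-fold higher in the maxilla and 1 in the mandible, so the list as a whole was not raised as Sox10 was. It also holds genes of neurons (Nefl, -2.92, and Gap43, 1.61). Its median thus does not measure Schwann cells alone and leaves them open as a source. Gland epithelium, in which Sox10 is also expressed, may be a source, but the test could not decide this. A separate list of gland regulators and transporters had a median of 2.561 over 9 genes (SD 2.09). Bhlha15 stood at 4.56 in the maxilla against -2.18 in the mandible and Spdef at 1.00 against -5.79. None of these genes is in another list used here, though several are also expressed in other epithelia. The nasal and salivary secretory list was also higher in the maxilla, by a median of 8.22. With such genes in the maxilla sample, the gland list would be raised whatever the source of Sox10. A difference of the bones themselves was not tested and stays open.

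Ucp1 was at least 213-fold higher in the ilium than in the femur, where it was not well above background, and 4.52 higher in the mandible than in the maxilla on the log2 scale. Mandible RNA carried into the ilium sample is argued against as the source of Ucp1, which stood 1.65 above its mandible level in the ilium. Tooth matrix genes stood a median of -7.688 from the mandible level there by measured signal. With the 5 not well above background there at their bound, this was at most -6.391 (SD 3.93 over 11 genes). The Ucp1 level alone settles the question, so the tooth matrix genes add no test. A smaller share of jaw RNA is not excluded: Amelx (-2.56) and Dspp (-3.81) were well above background in the ilium. For brown fat in the samples, the other brown adipocyte genes well above background in the bone with more Ucp1 had a median of 0.432 for ilium minus femur and of -0.349 for mandible minus maxilla. These values met the bounds set beforehand against brown fat, but it was seen only after the result that the bounds were ill chosen: 8 and 9 of the 9 genes were already well above background in the other bone, where a small share of brown fat would stay hidden. Cidea stood at 3.63 in the ilium and -1.29 in the femur, but at 1.41 in the mandible and 3.30 in the maxilla, against the direction of Ucp1 there, as did Otop1 (-5.89 and -1.84) and Elovl3, which that filter left out because only the maxilla (-2.32) showed it. Of the 9 genes, 3 were 2-fold higher in the ilium and 0 lower. In the mandible 2 were 2-fold higher (Cox8b and Cox7a1) and 4 lower (Cidea, Dio2, Otop1 and Ebf2). The skeletal muscle list was also higher in the mandible, with a median of -2.64 for maxilla minus mandible. Whether muscle raised Cox8b and Cox7a1 there was not tested, so these 2 genes cannot be counted towards brown fat. Brown fat stays open in both samples.

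The 4 blood cell lists and the cell cycle list were lower in the jaw bones. Scaling of the arrays is argued against, because the median nearest 0 of the 5 lists, less the median of all genes, was -1.687, under quantile normalization. Scalings by 1 constant per array cancel in this difference, so only quantile normalization and normexp could have changed it. Loss of 1 common share of marrow from all lineages would lower the 4 blood lists equally only if their genes were silent outside marrow, which was not tested. The lists did not fall equally: the erythroid median lay -1.491 from the B lymphocyte median, a pair picked as the extremes of 4 lists. The range of the 4 medians, 1.491, had a permutation p of 0.0136 over 51 genes with the extremes picked again in each permutation, though genes are not independent samples. This p does not measure the spread between bones, and loss of a common share stays open. A lower share of marrow with another mix of lineages, and a difference between jaw and other bones in the cells themselves, also stay open and were not tested.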
